A study of Homo sapiens with 6 samples.

How the data were processed

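Poly(A)-selected RNA was sequenced from CAL27, an established line from a human tongue squamous cell carcinoma, in 6 libraries. Per the labels, 3 libraries came from cells given a lentivirus carrying KLF7 and 3 from cells given a Mock lentivirus. The labels number the libraries 1 to 3 in each group and do not say whether they came from separate infections or cultures, so the p-values measure only the spread between these libraries, which may be technical.

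Per the file headers, the deposited table held 1 column of estimated counts and 1 column of FPKM for each library, over 195700 transcript rows. The estimated counts were not normalized, were not all whole numbers and differed in total between libraries. The deposited FPKM had 2 decimals and are scaled to transcript length and library total. Where a transcript had at least 500 estimated reads, 91.7% to 92.0% of the FPKM values per library could be recomputed within 1% from the estimated count, the spliced length in GENCODE 29 and the column total. The deposited length column was used for nothing, because 91.2% of its values equalled the genomic span with introns. The submitters' processing notes name hg38. The aligner, the quantifier, the gene annotation, the read length and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart.

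Every value column matched 1 sample by its library name, and 0 value columns had no sample. Estimated counts were summed over the transcripts of each gene symbol, which gave 55860 symbols, and rounded to whole numbers. Symbols are those of the deposited table, and 13 were date-like symbols damaged by a spreadsheet. Gene coordinates, biotypes, GC content and spliced lengths came from GENCODE 29 on GRCh38 through the transcript identifiers. Of these, 181388 (92.7%) were found there, and they carried 96.4% to 96.6% of the estimated reads per library.

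The plan made before the data were examined assumed a table of FPKM only, tested with limma, and named edgeR's quasi-likelihood test for the case that counts were present. The table held estimated counts per transcript, so the edgeR test on summed and rounded estimated counts became the main test and limma on FPKM an alternative. The fit used R 4.3.3 and edgeR 4.0.16 with TMM factors (0.954 to 1.06), filterByExpr with a minimum count of 10, glmQLFit and glmQLFTest, with all 6 libraries and no covariate. It tested 14074 genes, which held at least 99.9% of the reads of each library. P-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. Errors of log2 fold changes are standard errors computed as the absolute log2 fold change over the square root of the quasi-likelihood F. Levels are TMM-scaled CPM, counts scaled to library size, with the SD over 3 libraries. The KLF7 level in FPKM was also tested with an exact permutation test in R.

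A fold against a group with 0 reads in every library was computed against 3 reads in each of that group's libraries and is given as a lower bound. With 1 to 3 reads in a group, the ratio of the summed reads, scaled to library size, is given with a 95% counting interval. These intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

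Gene lists with fixed members, 32 in all, were written before the data were examined: KLF and SP family, mesenchymal genes, epithelial junction genes, partial-EMT genes of head and neck carcinoma, stemness markers, extracellular proteases, integrins and focal adhesion, squamous differentiation and cornification, basal keratinocyte genes, G1/S and G2/M genes, interferon-stimulated genes, NF-kB targets, hypoxia and glycolysis, YAP/TEAD, TGF-beta and BMP, Notch, Wnt, MAPK and AP-1, unfolded protein and integrated stress response, cholesterol and fatty acid synthesis, p53, NRF2, neuronal genes, cytosolic ribosomal proteins, oxidative phosphorylation, mitochondrially encoded transcripts, replication-dependent histones, and markers of fibroblasts, endothelium, leukocytes and simple epithelium. The 30 lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 30. Camera with an estimated correlation and fry were the alternatives.

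Named genes were KLF7, the 12 largest increases and 12 largest decreases past the threshold, 11 genes that the aim of the study points to, and at most 4 members of each list with the smallest p-value. The largest changes needed a mean FPKM of at least 1 in the higher group, no overlap between the libraries of the groups, and a symbol that is not a pseudogene, a clone name or date-like.

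The alternatives fixed beforehand were RLE factors, no filter on low counts, a mean FPKM of at least 5, DESeq2 1.42.0, the replicate number as a block, leaving out each library in turn, and limma on log2(FPKM + 0.5) for genes with a mean FPKM of at least 1. The limma fit was repeated with pseudocounts of 0.1 and 1, without a filter, with a mean FPKM of at least 5, with median centring, with quantile normalization, without the mean-variance trend and with robust estimation. Scaling by library totals only, and a per-library correction for transcript GC content and length, were added after seeing the data. Of the genes tested, 98.3% had a GC content and length.

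The fits were tested on counts simulated from the means, totals and dispersions of this comparison, over 14074 genes. Only a small share of these genes was changed, genes were drawn independently and no GC trend was put in. The false shares below therefore do not carry over to the real comparison, where 52.2% of genes passed. At 3 libraries per group edgeR recovered 67% of 100 genes changed 1.5-fold and 87% of 100 genes changed 2-fold, with 2.69% of its calls false. DESeq2 recovered 66% and 83% with 3.33% of its calls false. Limma on FPKM recovered 59% and 78% with 6.47% false (11 calls), above the 5% aimed at. For limma, genes dropped by its filter on a mean FPKM of at least 1 counted as not recovered. All these shares come from 1 simulated draw, which cannot fix a rate. Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for tables, the Gene Ontology test and figures. The series' design text also names a chromatin immunoprecipitation experiment, which was not analysed here.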

Results

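The transcriptome of CAL27 cells, a tongue squamous carcinoma line, was compared between 3 libraries from cells given a KLF7 lentivirus and 3 from cells given a Mock lentivirus. KLF7 is a zinc-finger transcription factor of the Krüppel-like family, and the series concerns migration and stemness in oral squamous cell carcinoma. Libraries held 18565289 to 20713130 estimated reads, with at least 10 reads for 13829 to 14116 genes. Log CPM correlated across genes at 0.990 to 0.991 within a group and at 0.960 to 0.969 between groups, and no pair of libraries agreed within sampling noise (chi-square per degree of freedom 4.45 to 14.5 within a group).

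The level of reads assigned to KLF7 was higher in every KLF7 library than in every Mock library. The cells' own KLF7 gene lies on chromosome 2 (207074137 to 207167267, minus strand, GRCh38). Reads of the lentiviral KLF7 and of this gene were not separated in the sum, which therefore does not give the change of the chromosomal gene. The KLF7 level was 54.8 ± 5.93 CPM (SD, n = 3) in KLF7 cells and 20.7 ± 0.661 CPM (SD, n = 3) in Mock cells, a log2 fold change of 1.40 ± 0.09 (edgeR quasi-likelihood test, adjusted p = 2.31e-09). On the deposited FPKM scale, summed over transcripts, the levels were 31.2 ± 5.36 and 3.14 ± 0.528, a ratio of 9.96. On log2(FPKM + 0.5) the difference was 3.12. A single KLF7 transcript held 43.4% of the gene's reads in KLF7 cells and 0.00142% in Mock cells. Its reads and FPKM imply a length of 1259 bases, against 7954 spliced bases in the annotation. A shorter length gives more FPKM per read, so the ratio of 9.96 is not a ratio of reads. The exact two-sided permutation p, computed on FPKM, was 0.10, the smallest that 3 against 3 libraries allow.

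**Figure D1:**
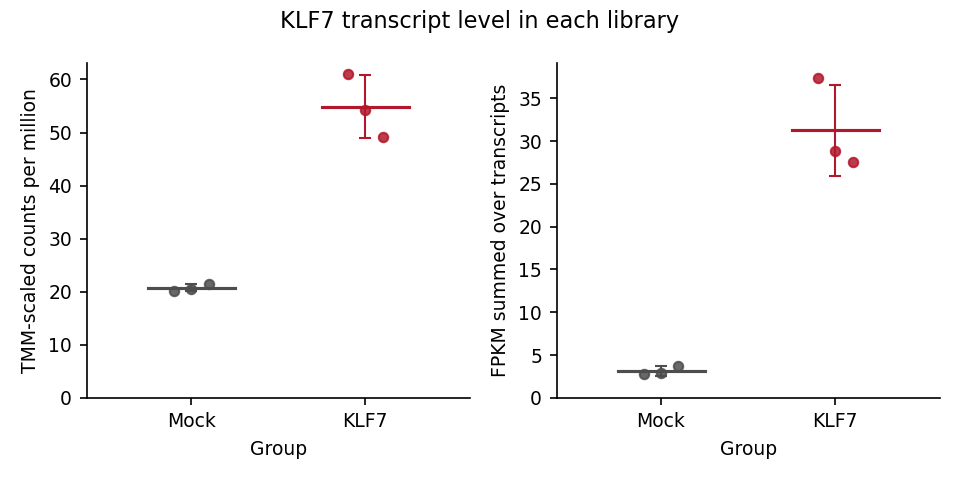
KLF7 in each library as TMM-scaled CPM (left) and as deposited FPKM summed over its transcripts (right), by group; points are libraries, lines are means and bars are SD (n = 3). The KLF7 libraries lie above the Mock libraries on both scales, by a ratio of 2.65 in CPM and of 9.96 in FPKM.

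Of 14074 genes tested, 7348 (52.2%) passed the threshold in edgeR with Benjamini-Hochberg adjustment, 3783 higher and 3565 lower in KLF7 cells. With an absolute log2 fold change of at least 1 as well, 1134 remained, 534 higher and 600 lower. The groups did not overlap for 59.3% of genes, where chance gives 10%. The direction of change followed GC content. The 11276 genes with a GC content and a mean of at least 50 reads were put into 5 bins of 2253 to 2258 genes by transcript GC content. In the lowest bin (30.6% to 42.2%) 1121 were higher and 81 lower, and in the highest (59.1% to 74.5%) 278 were higher and 1195 lower. Across all tested genes with a GC content (98.3%), which are not independent replicates, GC content and log2 fold change had a Spearman rho of -0.45. With a per-library correction for GC content and length, chosen after seeing the data, 6987 genes passed. Of these, 5161 passed in the same direction without the correction, 38 passed in the opposite direction and 1788 did not pass without it, while 2149 passed only without it. Scaling by library totals alone shifted the median log2 fold change of all genes from 0.03 to 0.15 and the share of calls that were higher in KLF7 from 51.5% to 65.4%. Directions given here are relative to the TMM scaling.

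**Figure D2:**
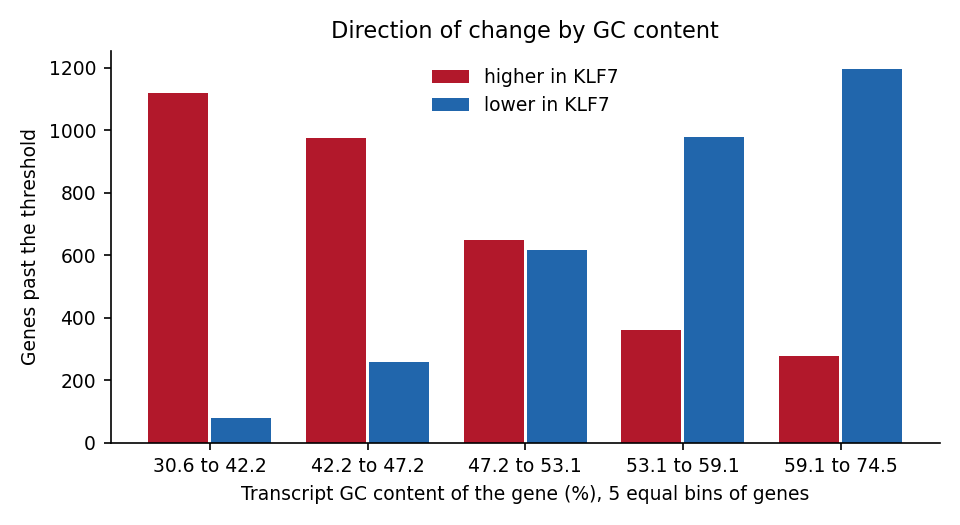
Number of genes past the threshold (vertical axis), higher (red) or lower (blue) in KLF7 cells, in 5 bins of transcript GC content (horizontal axis, percent), for 11276 genes with a mean of at least 50 reads. Higher calls fall from 1121 in the lowest bin to 278 in the highest, and lower calls go from 81 to 1195.

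Several of the largest increases were in genes of the cornified envelope, the cross-linked protein shell of outer squamous cells. SPRR2E had 237 estimated reads over the KLF7 libraries and 0 over the Mock libraries (at least 23.9-fold higher), SPRR2G had 129 and 0 (at least 12.9-fold higher), and CRCT1 had 91 and 0 (at least 9.10-fold higher). SPRR2D had 499 reads against 1, a ratio of 454 (95% counting interval 81.1 to 17956), and SPRR2A had 500 against 2, a ratio of 227 (62.6 to 1882). The SPRR2 genes are near-identical copies on chromosome 1, so how reads were split among them is uncertain. Summed over the 7 SPRR2 genes, the level was 21.9 ± 0.153 CPM in KLF7 cells and 0.0880 ± 0.0325 CPM in Mock cells (SD, n = 3). SPRR1B had a log2 fold change of 6.19 ± 0.36, SPRR1A of 4.95 ± 0.58 (148 reads against 4, all 4 in Mock library 1), and LCE3D had 67 reads against 2 (ratio 30.5, interval 8.11 to 257). APOBEC3A, a cytidine deaminase that acts on foreign DNA, had 251 reads against 0 (at least 25.3-fold higher), in transcripts that overlap APOBEC3B. The matrix metalloproteinase gene MMP10 rose by 5.70 ± 0.45 and the ferroxidase gene HEPHL1 by 5.28 ± 0.17 on the log2 scale. Over the alternatives SPRR1B ranged from 3.82 to 7.30, SPRR1A from 2.15 to 8.60, MMP10 from 1.69 to 6.91 and HEPHL1 from 2.56 to 5.47. These sizes depend on the scale and the libraries used. The constant that limma adds to FPKM shrinks differences where a group is near 0, as for HEPHL1 at 5.73 against 0.137 FPKM. The low ends therefore do not measure the spread between libraries. The same constant also narrows the differences of other low-level genes below. The chemokine gene CCL3, which has near-identical copies, had 52 reads against 1 (ratio 47.3, interval 8.12 to 1903). On log2(FPKM + 1) in limma the differences were smaller, at 3.67 for SPRR2D, 3.59 for SPRR2A, 2.76 for SPRR2E, 2.20 for SPRR2G, 1.95 for APOBEC3A and 1.63 for CRCT1. On log2(FPKM + 0.5) without a filter they were 2.05 for LCE3D and 1.598 for CCL3.

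Among the largest decreases, PCSK9, which promotes degradation of the LDL receptor, dropped from 236 ± 10.8 to 21.0 ± 2.72 CPM (SD, n = 3), a log2 fold change of -3.49 ± 0.09 (edgeR, adjusted p = 8.57e-14). NGFR, the low-affinity nerve growth factor receptor, dropped from 78.5 ± 0.732 to 9.26 ± 0.402 CPM (log2 fold change -3.08 ± 0.08). WNT4, a secreted Wnt ligand, went from 17.9 ± 0.913 to 2.47 ± 0.337 CPM, and PIGR, the polymeric immunoglobulin receptor, from 13.3 ± 0.749 to 1.44 ± 0.339 CPM. The proline dehydrogenase gene PRODH had a log2 fold change of -4.08 ± 0.39, the troponin gene TNNT3 of -3.84 ± 0.62, KNDC1 of -3.47 ± 0.37, LEMD1 of -3.39 ± 0.39, the serine protease gene HTRA3 of -3.31 ± 0.24, FOXO6 of -2.83 ± 0.26 and ENTPD8 of -2.82 ± 0.25. Over the alternatives PIGR ranged from -3.40 to -1.54, and these 7 from -4.73 to -1.93 for PRODH, -4.20 to -1.39 for TNNT3, -3.84 to -1.51 for KNDC1, -3.70 to -1.51 for LEMD1, -3.49 to -1.46 for HTRA3, -2.96 to -1.19 for FOXO6 and -2.98 to -1.19 for ENTPD8. SFT2D3 had 0 reads in KLF7 cells and 252 in Mock cells (at least 30.6-fold lower), and this value is uncertain because the gene overlaps WDR33 on the opposite strand; on log2(FPKM + 0.5) without a filter it was at -1.93.

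Genes that the aim points to moved in both directions. CD44, a hyaluronan receptor used as a stemness marker in oral carcinoma, rose from 1087 ± 58.1 to 1776 ± 68.4 CPM (SD, n = 3), a log2 fold change of 0.71 ± 0.06 (edgeR, adjusted p = 3.08e-08). CDH1, which encodes E-cadherin, fell by 0.31 ± 0.07 on the log2 scale (adjusted p = 0.00123), from 322 to 259 CPM; without a trend or a filter in limma on FPKM its adjusted p was 0.0758 and 0.0589. SNAI2, an EMT transcription factor, rose by 0.50 ± 0.10 (adjusted p = 0.000612), CDH2, which encodes N-cadherin, by 0.25 ± 0.10 (adjusted p = 0.0456) and BMI1 by 0.56 ± 0.17 (adjusted p = 0.0116). These 3 genes no longer passed with the correction for GC content and length. Their corrected log2 fold changes were 0.16 (adjusted p = 0.152) for SNAI2, 0.03 (0.736) for CDH2 and 0.17 (0.329) for BMI1. Over all alternatives their adjusted p ranged from 8.53e-06 to 0.152, from 0.00700 to 0.736 and from 0.00208 to 0.329. CDH2 passed in 9 of its 20 alternatives, and BMI1 did not pass without KLF7 library 2 (0.0819). VIM, which encodes vimentin, rose at a very low level, 0.751 ± 0.178 against 0.223 ± 0.119 CPM, and SOX2 fell at a very low level, 0.299 ± 0.0889 against 1.10 ± 0.487 CPM. In limma on FPKM without a filter VIM did not pass (adjusted p = 0.0682; over its 13 alternatives 0.00467 to 0.0682). The log2 fold change ranged over the alternatives from 0.46 to 2.17 for VIM and from -2.10 to -0.56 for SOX2. KLF4 fell by 0.70 ± 0.10 (adjusted p = 1.39e-05). MYC had a log2 fold change of -0.06 ± 0.07 (adjusted p = 0.478). ZEB1, with 5 reads over the KLF7 libraries and 2 over the Mock libraries, and ALDH1A1, with 19 and 26, were too low to test.

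**Figure D3:**
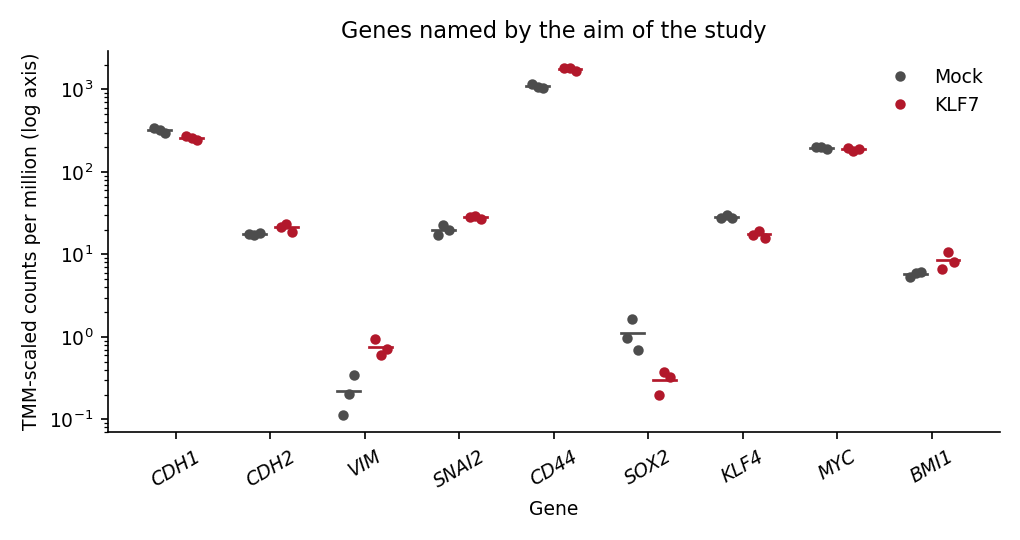
TMM-scaled CPM (log axis) of 9 genes that the aim of the study points to, in Mock (grey) and KLF7 (red) libraries; points are libraries and lines are means (n = 3). CD44 lies near 1776 CPM in KLF7 and 1087 CPM in Mock libraries, while the group means of VIM and SOX2 lie at or under 1.10 CPM.

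Gene lists were tested with camera at a preset correlation of 0.01, and 14 of 30 passed, 8 higher and 6 lower in KLF7 cells. With an estimated correlation 3 passed, namely cholesterol and fatty acid synthesis, interferon-stimulated genes and cornification. Fry, as used here, asks whether the members shifted on balance in 1 direction, without comparing them with other genes. Camera asks whether they shifted more than other genes. Where 52.2% of all genes passed, a list can pass fry without standing out from the other genes. With fry 20 passed, among them 6 that camera did not call. These were the mesenchymal (adjusted p = 0.0308; over all alternatives 0.0308 to 0.748), integrin (0.0244; 8.96e-05 to 0.701), YAP/TEAD (0.00573; 0.00573 to 0.618), unfolded protein (0.00127; 0.00127 to 0.991), NRF2 (0.0134; 0.0134 to 0.991) and neuronal lists (0.00127; 0.00127 to 0.820). Counts of members are given over all genes tested. The count adjusted over the list alone was the same except where given.

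Genes of cholesterol and fatty acid synthesis fell together. Of 30 measured, 27 fell, 0 rose and 3 did not pass (adjusted over the list alone, 27 fell and 1 rose), with a median log2 fold change of -0.90 (camera adjusted p = 2.05e-35, and adjusted p = 0.00400 with an estimated correlation). The stearoyl-CoA desaturase gene SCD dropped from 679 ± 32.4 to 140 ± 8.69 CPM, the fatty acid synthase gene FASN from 1780 ± 193 to 418 ± 52.9 CPM, and INSIG1, a sterol-regulated retention factor of the endoplasmic reticulum, from 207 ± 2.19 to 48.6 ± 3.52 CPM (SD, n = 3). Corrected for GC content, the median was -0.96.

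Interferon-stimulated genes rose. Of 39 measured, 32 rose, 3 fell and 4 did not pass, with a median of 0.90 (camera adjusted p = 3.36e-22, and adjusted p = 0.00455 with an estimated correlation). IFI27 rose from 17.6 ± 0.499 to 102 ± 3.52 CPM, IFI6 from 75.6 ± 4.27 to 273 ± 25.3 CPM, the antiviral GTPase gene MX1 from 99.4 ± 4.05 to 303 ± 3.47 CPM, and OAS2, a sensor of double-stranded RNA, from 46.6 ± 4.08 to 132 ± 5.66 CPM. Corrected for GC content, the median was 0.79.

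Of 26 genes of squamous differentiation and cornification, 19 rose, 3 fell and 4 did not pass, with a median of 1.88, which was also the median with 3 members without Mock reads set at their bounds (camera adjusted p = 3.38e-14, and adjusted p = 0.00914 with an estimated correlation). The ammonia transporter gene RHCG rose from 0.802 ± 0.105 to 18.1 ± 3.001 CPM (log2 fold change 2.89 to 4.63 over the alternatives) and S100A8 from 9.05 ± 0.495 to 34.1 ± 1.97 CPM. Of 16 basal keratinocyte genes 8 rose and 5 fell. KRT6A rose by 2.63 ± 0.08 and KRT16 by 1.94 ± 0.08 on the log2 scale, both keratins of activated keratinocytes, COL17A1 rose by 1.01 ± 0.06, and KRT14, the main basal keratin, fell by 1.15 ± 0.08 (camera adjusted p = 0.01002, and adjusted p = 0.290 with an estimated correlation). The basal list passed in 13 of 23 alternatives (0.000126 to 0.296), and not in limma on FPKM (0.281). Simple epithelial markers did not pass as a list (camera adjusted p = 0.491), with 2 of 8 higher, KRT7 by 0.48 ± 0.07 and FOXA1 by 0.53 ± 0.16. FOXA1 did not pass in limma with median centring (0.0566) or quantile normalization (0.0695; over all alternatives 0.00260 to 0.0695). After the correction for GC content 5 of the 8 were higher, and the list did not pass (adjusted p = 0.0762; over all alternatives 0.0550 to 0.919).

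Of 32 partial-EMT genes, a set described in head and neck carcinoma, 20 rose and 8 fell (adjusted over the list alone, 21 and 8), with a median of 0.54 (camera adjusted p = 1.93e-06, and adjusted p = 0.0680 with an estimated correlation). The laminin-332 gene LAMC2 rose from 1437 ± 58.0 to 4226 ± 168 CPM, LAMA3 by 1.26 ± 0.08, the plasminogen activator inhibitor gene SERPINE1 by 1.43 ± 0.07 and the urokinase gene PLAU by 1.08 ± 0.06 on the log2 scale. Of 24 extracellular protease and inhibitor genes 13 rose and 5 fell, among them MMP10 and ADAMTS1 (1.59 ± 0.11), with a camera adjusted p of 0.00113 and an adjusted p of 0.200 with an estimated correlation. This list did not pass in limma on FPKM (adjusted p = 0.262; over all alternatives 2.32e-05 to 0.409). Mesenchymal genes went both ways, with 5 of 20 higher and 10 lower (camera adjusted p = 0.4004). NT5E, the ecto-nucleotidase CD73, rose by 2.15 ± 0.08, while TAGLN fell by 1.89 ± 0.14, COL5A1 by 0.75 ± 0.08 (0.31 after the correction for GC content) and SPARC by 0.54 ± 0.05. Of 33 epithelial junction genes 16 rose and 11 fell (adjusted over the list alone, 17 and 11; camera adjusted p = 0.585), with PERP higher by 0.80 ± 0.07 (0.51 after the correction), TJP2 higher by 0.70 ± 0.08, and TJP3 and ELF3 at -2.14 ± 0.14 and -1.11 ± 0.08. Of 35 integrin and focal adhesion genes 15 rose and 11 fell (adjusted over the list alone, 16 and 11), with ITGA2 at 1.24 ± 0.09 and TNS3 at -0.90 ± 0.07, or -0.57 after the correction (camera adjusted p = 0.166). With the correction for GC content this list passed (adjusted p = 8.96e-05; over all alternatives up to 0.701).

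Stemness markers did not pass as a list. Of 16 measured, 6 rose and 6 fell, the median was 0.02 and the mean -0.23 (camera adjusted p = 0.491). Besides the markers above, ALDH3A1 had a log2 fold change of -1.93 ± 0.16, the telomerase gene TERT of -1.05 ± 0.10 and NOTCH1 of -0.81 ± 0.09. Corrected for GC content, TERT was at -0.71 and NOTCH1 at -0.30. Of 16 Notch pathway genes 12 fell and 1 rose (adjusted over the list alone, 13 and 1), with NOTCH3 at -1.99 ± 0.11, the ligand genes DLL1 and JAG1 at -1.12 ± 0.07 and -0.73 ± 0.07, and NRARP at -0.84 ± 0.09 (camera adjusted p = 1.14e-05, and adjusted p = 0.200 with an estimated correlation). The median member of this list had a GC content of 58.8%, and its median log2 fold change was -0.63 before and -0.34 after the correction for GC content.

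Of 29 MAPK feedback and AP-1 genes 16 rose and 4 fell (camera adjusted p = 1.38e-05, and adjusted p = 0.229 with an estimated correlation). HBEGF and TGFA, both ligands of the EGF receptor, rose by 1.39 ± 0.07 and 1.21 ± 0.08, the AP-1 subunit gene FOSL1 by 1.27 ± 0.08 and the phosphatase gene DUSP4 by 1.02 ± 0.07. Of 31 NF-kB target and cytokine genes 15 rose and 4 fell. CSF2 rose by 2.34 ± 0.07 and IL24 by 3.74 ± 0.22 (2.18 to 3.85 over the alternatives), while CCL2 and TNFAIP2 fell by 1.32 ± 0.07 and 1.15 ± 0.06. Its camera adjusted p was 0.01002, with an adjusted p of 0.191 with an estimated correlation and of 0.0779 with the correction for GC content, and the list passed in 12 of 23 alternatives (0.000782 to 0.407).

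Of 31 G1/S genes 21 rose and 5 fell, with FEN1, RAD51 and PCNA at 0.68 ± 0.07, 0.67 ± 0.08 and 0.62 ± 0.08 and the helicase gene MCM2 at -0.58 ± 0.06 (camera adjusted p = 0.00875, and adjusted p = 0.200 with an estimated correlation). After the correction for GC content 14 rose and 6 fell, the median went from 0.37 to 0.18 (adjusted p = 0.0484), and PCNA and MCM2 were at 0.34 and -0.35. With a filter on mean FPKM of at least 5 the list did not pass (adjusted p = 0.0662 in edgeR and 0.0565 in limma), and it passed in 20 of 23 alternatives (0.000280 to 0.200). Of 33 G2/M genes 10 rose and 8 fell (camera adjusted p = 0.750), with CDK1 at 0.51 ± 0.09, KIF20A at -0.69 ± 0.08, CDC25C at -0.43 ± 0.10 and CDC20 at -0.37 ± 0.06. After the correction 1 G2/M gene rose and 13 fell, with a median of -0.14 (adjusted p = 0.0762; over all alternatives 0.0762 to 0.985), CDK1 was at 0.03 (adjusted p = 0.750; over all alternatives 8.53e-08 to 0.750), and CDC25C and CDC20 were at -0.66 and -0.24. Of 11 replication-dependent histone genes 3 rose, namely HIST1H1C, HIST1H2AC (0.81, or 0.42 after the correction) and HIST1H2BD, and HIST1H1E fell (camera adjusted p = 0.4004). The HIST1H1E levels of the groups overlapped, and this gene passed in 12 of 20 alternatives (adjusted p 0.000334 to 0.180), not with the correction for GC content (0.0648).

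Of 35 cytosolic ribosomal protein genes 28 fell and 1 rose (adjusted over the list alone, 28 and 2), with a median of -0.32 (camera adjusted p = 1.53e-06, and adjusted p = 0.200 with an estimated correlation). RPS3, RPS2, RPS9 and RPS5 lay between -0.64 and -0.59 with standard errors of 0.05 to 0.06 (over the alternatives up to -0.18 for RPS2, -0.34 for RPS5 and -0.35 for RPS9). With quantile normalization of FPKM the median was -0.16 and the list did not pass (adjusted p = 0.0667; over all alternatives 1.52e-09 to 0.200). Of 13 mitochondrially encoded transcripts 10 fell and 0 rose, with a median of -0.39 (camera adjusted p = 0.00113, and adjusted p = 0.608 with an estimated correlation), and they made up 2.97% to 3.06% of reads in KLF7 libraries and 3.41% to 3.88% in Mock libraries. MT-CO1 fell by 0.49 ± 0.05 and MT-CO3 by 0.55 ± 0.05 (0.35 to 0.74 over the alternatives), but with quantile normalization of FPKM MT-CO1 was at 0.03 (adjusted p = 0.600; over all alternatives 6.40e-24 to 0.600) and MT-CO2 at -0.05 (0.412; 6.35e-20 to 0.412). There the list median was -0.13 and the list did not pass (adjusted p = 0.364). It passed in 21 of 23 alternatives (1.02e-06 to 0.608), and its median was -0.67 after the correction for GC content. Of 31 nuclear genes of oxidative phosphorylation 15 fell and 3 rose, with ATP5B, NDUFV1, CYC1 and COX5B between -0.53 and -0.46 (NDUFV1 and CYC1 at -0.33 and -0.30 after the correction; camera adjusted p = 0.0400, and adjusted p = 0.200 with an estimated correlation). Scaled by library totals this list did not pass (adjusted p = 0.122; over all alternatives 0.00247 to 0.200, with 9 of 23 past the threshold).

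**Figure D4:**
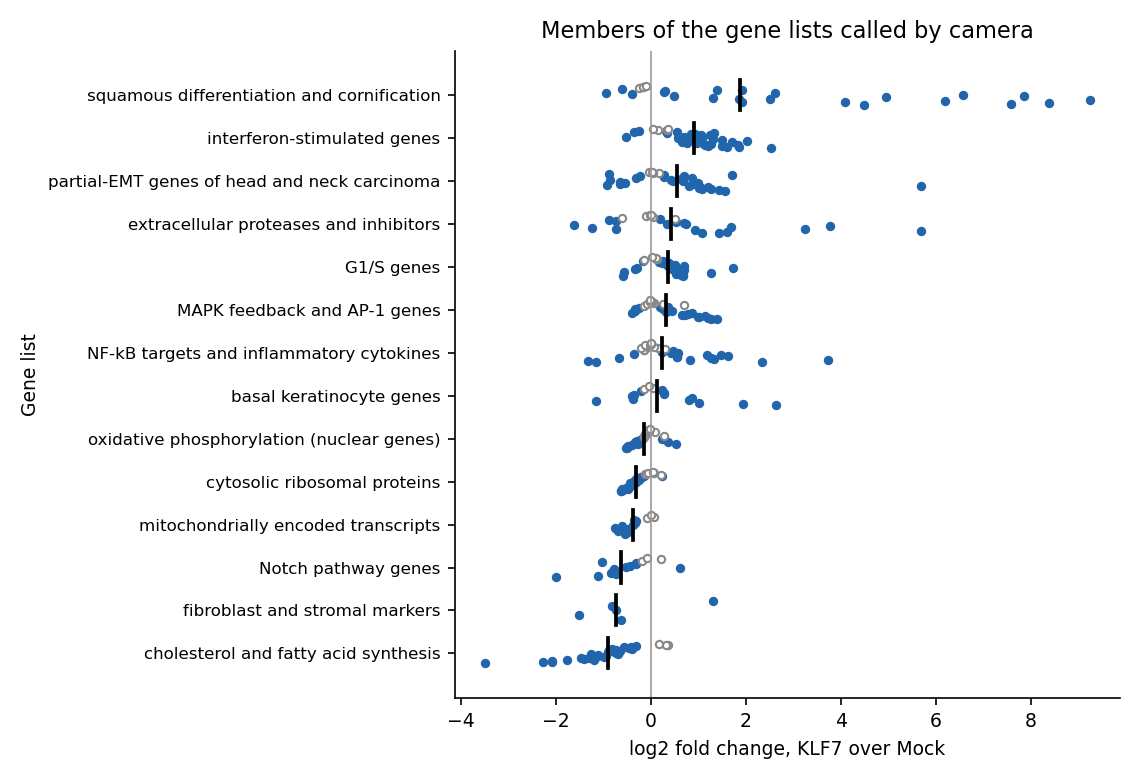
Log2 fold change of KLF7 over Mock (horizontal axis) for each measured member of the 14 gene lists called by camera (vertical axis); filled points passed the adjusted threshold in edgeR, open points did not, and black bars are list medians. Medians range from -0.90 for cholesterol and fatty acid synthesis to 1.88 for cornification, and the farthest points rest on few or 0 Mock reads.

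The other lists did not pass, and their members moved in both directions. Among hypoxia and glycolysis genes 12 of 32 rose and 13 fell (camera adjusted p = 0.516), with ANGPTL4 at 3.41 ± 0.15 and ALDOC, DDIT4 and CA9 at -1.88 ± 0.08, -1.50 ± 0.06 and -1.31 ± 0.07. Among genes of the unfolded protein and integrated stress response 11 of 31 rose and 10 fell (adjusted over the list alone, 12 and 11), with SESN2, DDIT3 and PHGDH between -1.24 and -0.97 (camera adjusted p = 0.166). With the correction for GC content this list passed as lower (adjusted p = 0.0181; over all alternatives 0.00127 to 0.991), with a median of -0.06 against 0.08 without it. Among p53 targets 7 of 23 rose and 6 fell (camera adjusted p = 0.906), with CDKN1A, C12orf5 and AEN at 0.86 ± 0.07, 2.38 ± 0.22 and 1.02 ± 0.10 and GDF15 at -1.66 ± 0.08. Among NRF2 targets 8 of 24 rose and 7 fell (camera adjusted p = 0.585), with the transketolase gene TKT at -1.09 ± 0.06. Among YAP/TEAD targets 3 of 24 rose and 12 fell (camera adjusted p = 0.176), with TGFB2 at -1.09 ± 0.10 (-1.42 to -0.72 over the alternatives) and AJUBA and IGFBP3 at -0.73 ± 0.06 and -0.73 ± 0.05. Among TGF-beta and BMP targets 6 of 19 rose and 9 fell (camera adjusted p = 0.955), with PMEPA1 at 1.93 ± 0.08, INHBA at 1.20 ± 0.08 and ID1 at -0.95 ± 0.07. Among Wnt targets 5 of 16 rose and 5 fell (camera adjusted p = 0.616), with CCND1 and DKK1 at 0.73 ± 0.07 and 0.93 ± 0.11, the latter 0.59 after the correction for GC content. TCF7 was at -0.70 (edgeR, adjusted p = 0.00121), and did not pass in limma on FPKM without a filter (adjusted p = 0.0556). Among neuronal and axon growth genes 7 of 18 rose and 6 fell (camera adjusted p = 0.491), with MAP1B at 2.88 ± 0.16 (1.11 to 3.09 over the alternatives), TUBB3 at 1.42 ± 0.08 and SEMA3F at -1.78 ± 0.09. Among KLF and SP genes 5 of 16 rose and 6 fell (camera adjusted p = 0.906), with KLF6 at 0.88 ± 0.09 and KLF15 at -1.58 ± 0.33 (-1.93 to -0.71 over the alternatives). Median, mean and test differed in sign for the unfolded protein, p53, KLF and SP, stemness, Wnt and hypoxia lists.

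Markers of other cell types were few. Of 13 fibroblast markers 5 were measured, of which 4 fell and 1 rose, with PDGFRB at 7.03 CPM in Mock cells and 2.46 CPM in KLF7 cells, a log2 fold change of -1.68 to -0.62 over the alternatives (camera adjusted p = 0.0362, and adjusted p = 0.354 with an estimated correlation). With the correction for GC content this list did not pass (adjusted p = 0.1002; over all alternatives 0.00337 to 0.354). Endothelial and leukocyte markers were too few to test as lists. CDH5 and VWF were lower, at log2 fold changes of -0.72 ± 0.08 and -2.15 ± 0.29 (VWF -2.38 to -0.50 over the alternatives), CD68 and CSF1R were higher by 0.66 ± 0.08 and 0.65 ± 0.15, and CD14 was at -0.17 ± 0.15 (edgeR, adjusted p = 0.366).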

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

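The test of culture density and the corrections for GC content and scaling by library totals were chosen only after results had been seen. The other tests of explanations in this section were written down before their results were seen.

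The estimates for single transcripts of KLF7, which the comparisons of gene totals do not use, held a signal in KLF7 libraries that was near 0 in the Mock libraries. Transcript ENST00000412414 had 499 ± 74.6 estimated reads in KLF7 libraries (SD, n = 3) and 0 after rounding to 1 decimal in each Mock library (0.00142% of KLF7 reads there), and ENST00000435602 had 45.2 ± 13.9 against 0.200 ± 0.346. ENST00000309446, which held 89.4% of KLF7 reads in Mock libraries, had 461 ± 49.4 reads in KLF7 libraries against 353 ± 18.0. These reads are not scaled to library size. The lentivirus carried KLF7, and whether the reads near 0 in Mock libraries came from it was not tested.

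Of the 10 splits of the 6 libraries into 3 and 3, only the real one (1 of 10) gave as many genes, 7348 by edgeR against 0 in each other split, and as many lists by camera with a preset correlation, 14 against at most 10. In the other splits 60 to 361 genes had an unadjusted p under 0.05 in edgeR, DESeq2 called 0 to 2 and limma on FPKM 0. With 10 splits no share under 0.05 can be reached. Each other split puts KLF7 and Mock libraries on both sides, so the group difference adds to the spread within a side. A wide group difference then leaves few or 0 genes to be called, so that 0 does not measure false calls. Such splits also keep part of the group difference, so their lists are not a count without a group effect. The 10 lists called in 1 of them are still to be set beside the 14. In the real split 3 lists passed with an estimated correlation.

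GC-rich transcripts were lower in KLF7 libraries, by 0.27 on the log2 scale for each 10 points of GC content across 11276 genes. A GC bias of the libraries is a candidate explanation. The slope among transcripts of the same gene, over 4816 genes, was -0.43, 1.64 times the slope of -0.26 between these same genes. The 95% bootstrap interval of this ratio was 1.44 to 1.83, where a trend between genes alone was predicted to give a ratio under 0.5. The prediction set no upper limit, so it does not account for a steeper slope within genes than between them. The interval resampled genes with the between-gene slope held fixed, so it leaves out the spread between libraries. How reads were split among transcripts was not controlled. A GC slope that varies from library to library cannot be told apart from a group difference, because the slopes of the groups did not overlap (-0.25 to -0.05 for KLF7 and 0.10 to 0.17 for Mock libraries) but the gap between groups was only 0.698 of the widest range within a group. A biological effect of KLF7 on GC-rich genes stays open as untested. The labels give no library batch.

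Genes of cholesterol and fatty acid synthesis were lower in KLF7 cells. The tables argue against GC content or length as the whole cause, since the corrected median was -0.96 against -0.90 before. Under library totals and RLE factors the third quartile of the members stayed at -0.47 or lower. These scalings move all genes little, with medians over all genes of 0.15 and 0.02 against 0.03 with TMM. That check could hardly have failed, and shows only that the choice among these scalings does not account for the fall. A change in total RNA per cell was not tested. A denser culture of the KLF7 cells may lower such genes and stays open, since YAP/TEAD targets, which fall in dense cultures, gave a camera adjusted p of 0.176 and passed in 1 of 23 alternatives, fry (0.00573; over all alternatives 0.00573 to 0.618), with a median of -0.19. G1/S genes, which also fall there, do not settle it, as they were called higher (0.00875) but not with an estimated correlation (0.200; over all alternatives 0.000280 to 0.200), and their median went from 0.37 to 0.18 with the GC correction. An effect of KLF7 itself also stays open, as a hypothesis that the labels' groups cannot separate from culture conditions.

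Interferon-stimulated and cornification genes were higher in KLF7 cells. GC content or length is argued against as the whole cause, with corrected medians of 0.79 and 1.86 against 0.90 and 1.88. Reads shared between paralogs are argued against as the whole cause for cornification. Of the 8 members outside multigene families 6 rose and 1 fell. Their median was 3.29, or 2.20 with members without Mock reads at their bounds. These 8 do not show how reads were shared within the families. The sum over the SPRR2 genes, 1378 reads against 5, does not depend on the split among them, and sharing within the other families was not tested. Interferon made by the KLF7 cells may raise the interferon-stimulated genes and stays open, since 0 of 21 interferon genes had over 3 reads in every KLF7 library and more than in every Mock library, counts too few to decide it (IFNB1 had 4 reads in 1 KLF7 library and 0 elsewhere). An unequal lentiviral load of the groups was not tested.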

How the results depend on the processing

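Scaling by library totals and the correction for GC content and length were chosen after seeing the data. Without exception the KLF7 increase and the cholesterol, interferon-stimulated and cornification lists kept direction and passed in each alternative run. Of 140 named genes past the threshold, 126 passed in the same direction in every alternative that tested them. Most of these were picked for large changes or small p-values in these same data, so this share does not describe all genes. Over all genes, 5161 of 7348 passed in the same direction with the GC correction alone. DESeq2 gave no list test. The count of genes was 6788 with DESeq2, 7316 with RLE factors, 7468 without a filter and 4955 at a mean FPKM of at least 5. Leaving out each library in turn gave 6257 to 7465 genes (3187 to 3863 higher, 3070 to 3602 lower), 13 to 15 lists and a KLF7 log2 fold change of 1.32 to 1.48. Same-numbered libraries did not deviate together (correlations 0.014, -0.043 and 0.034), and a replicate block gave 7161 genes, 13 lists and 1.40 for KLF7, with 1 of 3 KLF7 libraries correlating best with its own number. With an absolute log2 fold change of at least 1, 1134 genes passed, by construction. With an estimated correlation 3 lists passed, and fry called 20. The limma fits on FPKM split their calls as 61.8% to 64.6% higher, against 51.5%, except with median centring (49.1%) or quantile normalization (49.4%). Genes lower in KLF7 numbered 2279, 2267 and 2271 at pseudocounts of 0.5, 0.1 and 1, 2124 without a filter, 1806 of 4726 at a mean FPKM of at least 5, 2084 without a trend and 2277 with robust estimation. Lists called numbered 9 at each pseudocount, without a trend and with robust estimation, 8 at a mean FPKM of at least 5 and 7 with quantile normalization. Median centring alone took the share of higher calls on log2(FPKM + 0.5) from 63.6% to 49.1%. The scaling between libraries thus accounts for that split. A mean FPKM of at least 5 tests fewer genes, and for the shifts in the number of lists the cause was not tested. Genes with few reads are limited by depth, as for ZEB1 and ALDH1A1.

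Values near 0 changed sign, and the cause was not tested. In log2 units, MYC was at 0.058 with library totals, 0.014 with the GC correction, 0.049, 0.049 and 0.048 at limma pseudocounts of 0.5, 0.1 and 1, 0.049 in limma without a filter, at a mean FPKM of at least 5, without a trend and with robust estimation, and 0.012 with quantile normalization. CD14 was at 0.045, 0.051 and 0.040 at those pseudocounts and 0.045 without a filter, without a trend and with robust estimation. MT-CO1 was at 0.035 with quantile normalization.

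Medians of 13 of the 16 lists not called changed sign somewhere. With library totals the KLF and SP list was at 0.099, hypoxia at 0.027, Wnt at 0.067 and NRF2 at 0.035. With the GC correction KLF and SP was at 0.014, G2/M at -0.14, Wnt at 0.052 and the unfolded protein list at -0.059. Without a count filter stemness was at -0.044 and simple epithelium at -0.039. At a mean FPKM of at least 5 KLF and SP was at 0.0041, junction genes at -0.056, stemness at -6.5e-05, Wnt at 0.018 and p53 at -0.094. In limma at pseudocounts of 0.5, 0.1 and 1, KLF and SP was at 0.18, 0.19 and 0.18, hypoxia at 0.0098, 0.0098 and 0.0098, TGF-beta at 0.032, 0.032 and 0.032, Wnt at 0.049, 0.049 and 0.048, NRF2 at 0.054, 0.056 and 0.052, and neuronal genes at 0.043, 0.049 and 0.038, and without a trend or with robust estimation at the values for 0.5. Without an FPKM filter KLF and SP was at 0.11, mesenchymal genes at 0.073, hypoxia at 0.022, TGF-beta at 0.023, Wnt at 0.041 and NRF2 at 0.042. In limma at a mean FPKM of at least 5 KLF and SP was at 0.058, Wnt at 0.096, p53 at -0.014 and NRF2 at 0.042. With median centring KLF and SP was at 0.077, stemness at -0.021 and p53 at -0.037, and with quantile normalization KLF and SP was at 0.058, stemness at -0.0024, hypoxia at 0.022 and p53 at -0.014. Leaving out 1 library gave KLF and SP medians from -0.0084 to 0.032 and stemness medians from -0.059 to 0.14.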

Other observations

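MHC class II genes, which encode the molecules that present peptides to helper T cells, were lower in KLF7 cells. Of 9 measured, 8 fell and 0 rose, with a median log2 fold change of -1.33. HLA-DRA fell from 153 ± 9.38 to 54.4 ± 0.561 CPM (SD, n = 3), and HLA-DMB from 22.2 ± 0.912 to 8.72 ± 0.223 CPM. HLA-DRB1 had a log2 fold change of -1.33 ± 0.16 and HLA-DPB1 of -2.16 ± 0.28. HLA-DOB was at 0.21 ± 0.32 (edgeR, adjusted p = 0.594). With the correction for GC content and length 8 of 9 again fell. These genes were chosen after their values had been seen, from the enrichment below. Several of them are polymorphic paralogs, so how reads were split among those is uncertain.

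Terms of the deposited Gene Ontology annotation were tested, after the data had been seen, among genes that changed at least 2-fold, against 10084 genes with a term, over 1298 terms with a one-sided hypergeometric test. Among higher genes, epidermis development led with 15 of 52 genes against 1.91 by chance (adjusted p = 3.89e-07), followed by keratinization with 8 of 17 (3.67e-05) and defense response to virus with 15 of 103 (0.00213). SPRR2E, SPRR2D, SPRR2G, SPRR2A, SPRR1B and SPRR1A count in both of the first terms. The test treats them as independent genes, although the split of reads among the SPRR2 copies is uncertain. The inflammatory response had 19 of 170 (0.00391) and the immune response 18 of 160 (0.00468). Among lower genes, cell adhesion had 25 of 242 (adjusted p = 0.00983) and brown fat cell differentiation 7 of 22 (0.00983, and 0.0156 with GC-corrected values). The immune response again had 18 of 160 (0.0278) and cholesterol biosynthetic process 7 of 29 (0.0283). Cell adhesion did not pass among higher genes (16 of 242, adjusted p = 0.440), but with GC-corrected values it did (20 of 242, 0.00868). With GC-corrected values 12 terms passed among higher genes, against 11 before, and 7 among lower genes, against 5 before. Terms gained also included extracellular matrix organization among higher genes (adjusted p = 0.00884) and isoprenoid biosynthetic process among lower genes (0.00811). With GC-corrected values 4 terms no longer passed. Among higher genes these were defense response to Gram-negative bacterium (adjusted p = 0.165, before 0.00468), cellular response to lipopolysaccharide (0.156, before 0.0264) and proteolysis (0.316, before 0.0279), and among lower genes the neuropeptide signaling pathway (0.186, before 0.0283).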
